A study of Mus musculus with 4 samples.

How the data were processed

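Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and the cut fragments are sequenced, in cells of mouse fetal liver at embryonic day 14.5. Per the labels, nuclei were treated by the Omni-ATAC protocol, and 4 libraries were made: 2 from wild-type (WT) livers and 2 from livers of Hemgn knockout (KO) mice. Hemgn encodes hemogen, a nuclear protein of blood-forming cells. The labels do not say whether replicates came from separate embryos or litters, so the spread between these libraries may be technical. Only the exact tests of library values measure this spread. All other p-values are computed over regions or genes and do not contain it.

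The deposited files were 4 peak lists, 1 per library and none pooled, laid out as MACS2 narrowPeak tables. Per the submitters' processing notes, Bowtie2 2.3.5, SAMtools 1.9, Picard 2.21.4 and MACS2 2.2.7.1 were used; their roles and settings, and the genome build, are not given in the sources used here. The deposited score was 10 times the −log10 q, without its decimals, per the file values. The deposited fold enrichment is the authors' ratio of fragments at the summit to the background at that peak in the same library, with 1 added to both. The deposited −log10 p and −log10 q are likewise the authors' values for each peak, and the highest q in any list was 0.0489. These values belong to single lists: they were used to rank and filter peaks within a list and to recover each library's background. Fold was not compared between libraries as a height, but within-list percentiles of fold were set side by side, as at some globin regions. A cut at a fold of at least 6 falls at a different place in each list. Median folds were 5.29 and 6.31 in WT replicates 1 and 2, and 5.90 and 5.42 in Hemgn KO replicates 1 and 2. Names of single peaks inside the lists carry other replicate numbers than the labels, and the labels were followed.

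Depth is not stated in a peak list. MACS2 fold and −log10 p together give the background, which was taken as a measure of relative depth. The background stands for depth only if settings and fragment lengths were alike in all libraries, which is not given. For peaks with a −log10 p under 60, the whole number of fragments and the background that return both values were solved for, with a tolerance of 0.001 on the −log10 p; 100% of these peaks had a solution in all 4 lists. The most frequent background in a library, in fragments, was then used as the library's background and its relative depth. It was the background of 45.2% and 30.2% of these peaks in WT replicates 1 and 2. In Hemgn KO replicates 1 and 2 the shares were 32.7% and 35.3%. On 2000 simulated peaks with a known background, 100% came back within 0.01.

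Peaks on chromosomes 1 to 19, X and Y were used. The 4 lists were merged into 55290 regions wherever peaks shared at least 1 bp, and each region was scored as present or absent in each library. A region was called WT-only when both WT libraries and no KO library had a peak there, and KO-only in the opposite case. A region's rank was the lower of its 2 libraries' within-list percentiles of fold. For gene counts and list tests, summits were assigned to the nearest boundary of a protein-coding gene within 100 kb, and the strongest regions were named by the nearest boundary at any distance, from a RefSeq gene table of the mouse assembly GRCm38.p6 (21770 genes after genes on alternate-strain scaffolds were left out). The build of the lists is not given in the sources used here, so no coordinate of the gene table is printed, and coordinates are those of the lists, counted from 1. Between 27.8% and 35.3% of summits lay within 1 kb of a gene boundary of that table, against 6.63% to 7.28% after shifts of 5, 20 and 50 kb. The table has no strand and no exons. The planned promoter class (1 kb around a transcription start) was therefore replaced by a gene-boundary class, within 1 kb of either end of a gene, and regions elsewhere were only placed inside or outside a gene. Motif tests were planned but not run, since no genome sequence was used here.

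Library values were compared by an exact two-sided permutation test; 2 against 2 libraries have 6 relabelings, and the smallest p they allow is 0.333. Region counts have no p, because the 4 libraries make only 3 splits into pairs, and the counts of the other splits are given instead. Shares of regions were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 16 gene lists, over 32 tests of lists and directions, or over 21 chromosomes; regions are not replicates, so these tests describe these 4 libraries. The background for the 32 tests was every region found in both libraries of at least 1 genotype. The 16 lists (300 genes, each in 1 list) covered globin, heme and iron, red cell membrane, erythroid regulators, the BAF complex, organelle clearance, cell cycle, apoptosis, stem and progenitor cells, megakaryocytes, macrophages, granulocytes and mast cells, hepatocytes, lymphocytes, endothelial and stellate cells, and housekeeping genes. Samples, tests, lists and the naming rule were fixed before the data were examined. Named were Hemgn and the globin loci with 50 kb on each side; the 10 WT-only and 10 KO-only regions of highest rank; up to 30 list genes with an exclusive region at a gene boundary; the 5 genes per direction with the most exclusive regions; and up to 4 genes per list with the most. Intervals are 95% (exact binomial for shares, Woolf for odds ratios) and cover counting error only.

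Alternatives were the upper 50% of each list by fold, lists of equal length (34181 peaks, the shortest list), overlap by 50% of the shorter peak, windows of 250 bp on each side of summits, autosomes alone, a gap of 500 bp to the nearest peak of the other genotype, a −log10 q of at least 5, boundary spans of 500 bp and 2.5 kb, gene assignment within 20 kb, stratification by 5 classes of region score, 10000 random gene lists, and each library left out in turn. Lists of equal length by q, the top 20000 peaks by fold or by q, a fold of at least 6, and all settings of the 32 tests other than score classes and random gene lists were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The functions were tested on simulated data for the comparison of WT with KO: 34181 peaks with 200 regions planted in each direction gave back 398 of 400 (99.5%), a planted list of genes passed each list test, and 0 of the 16 lists that were not planted did. Each simulated library kept a random 95% of the other peaks of the same list, without a difference in depth. The simulation therefore cannot show false calls that come from depth.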

Results

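Open chromatin was compared between WT and Hemgn KO fetal livers at embryonic day 14.5, when the liver is the main site of red cell production. The series title names cooperation between hemogen and BRG1, the ATPase of the BAF chromatin remodelling complex, at promoters and enhancers. The question of the comparison is which accessible regions differ between the genotypes. WT replicate 1 had 47858 peaks on the chromosomes, WT replicate 2 had 34181, Hemgn KO replicate 1 had 35426 and Hemgn KO replicate 2 had 43018. Peaks covered 32.1, 24.2, 25.5 and 30.5 Mb in the same order. Backgrounds were 5.67, 2.29, 2.49 and 3.8 fragments, a 2.48-fold range, and set the lowest fold a peak could have at the library background at 2.40, 3.04, 2.87 and 2.71.

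The targeted gene is given before all others. Within 50 kb of Hemgn on chromosome 4, the libraries had 13 and 12 peaks in WT and 12 and 14 in KO, and 11 of 15 merged regions were present in all 4 libraries. A region at the gene's boundary (chromosome 4, 46403640 to 46405019) and a region inside or next to the gene (46395660 to 46396905) had a peak in every library, KO included. No region of this locus was WT-only or KO-only. The kind of KO allele is not given in the labels, and accessibility of the locus does not measure the gene's product, so these peaks check nothing about the labels.

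**Figure D1:**
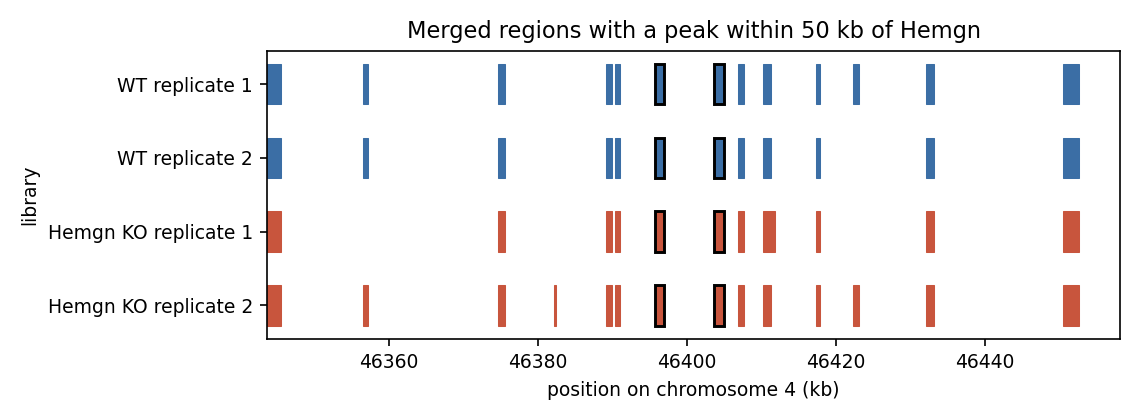
Position on chromosome 4 in kb (x axis) of the merged regions with a peak within 50 kb of Hemgn in each of the 4 libraries (y axis; blue, WT; red, Hemgn KO; black outline, regions at or within 1 kb of Hemgn). Both outlined regions are present in all 4 libraries, as are 11 of the 15 regions.

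The globin loci had peaks in both genotypes, which does not show that their accessibility was equal. In the alpha-globin locus on chromosome 11, 19 of 26 regions were present in all 4 libraries, with 25 and 24 peaks in WT and 22 and 23 in KO. One region near Hba-a1 (32283252 to 32283465) was WT-only and 1 near Hba-a2 (32295879 to 32296334) was KO-only, both in the lowest ranks of their lists (percentiles 1.5 and 2.0). Hba-a1 and Hba-a2 are near-identical copies, so the placement of reads between them is uncertain. Within-list percentiles of fold at the Hbq1a boundary region were 0.747 and 2.58 in WT and 49.3 and 33.1 in KO. At the Hbq1b boundary region they were 5.85 and 9.94 in WT and 46.3 and 30.2 in KO. Hbq1b lies by Hba-a1 and Hbq1a by Hba-a2, so both boundary regions may share reads and need not be independent, which was not tested. Other regions went the other way, such as 1 by Hba-a2 and Hbq1a (38.1 and 26.5 in WT, 5.76 and 22.4 in KO). These regions were picked after seeing the data and the differences were not tested. In the beta-globin locus on chromosome 7, 14 of 20 regions were present in all 4 libraries, with 17 and 14 peaks in WT and 16 and 16 in KO, and 0 were exclusive to a genotype. At both adult beta-globin genes, Hbb-bs and Hbb-bt, every library had a boundary peak.

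No difference between the genotypes in peak number or in the kind of place where peaks lay was detectable with these 4 libraries. Peak number averaged 41019.5 ± 9671 in WT and 39222 ± 5368 in KO (SD, n = 2 each; exact permutation p = 1, smallest possible 0.333). Covered length averaged 28.2 ± 5.57 Mb in WT and 28.0 ± 3.50 Mb in KO (SD, n = 2 each; exact permutation p = 1). The share of peaks at gene boundaries was 27.8% and 35.3% in the WT libraries and 34.7% and 29.7% in the KO libraries, with means of 31.5% ± 5.32 and 32.2% ± 3.48 (SD, n = 2 each; exact permutation p = 1). In both measures the 2 libraries of a genotype differed by more than the genotypes did. Peak number followed the background, and the KO mean was higher by 5041 peaks without WT replicate 1 and by 1998.5 without Hemgn KO replicate 1. The boundary share of KO was lower without either of those libraries, with a KO minus WT difference of -3.09 and -1.79 percentage points.

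**Figure D2:**
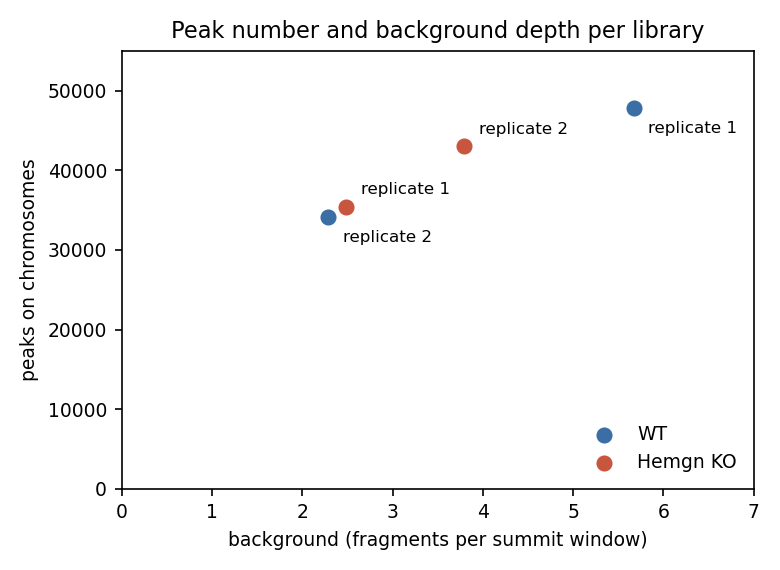
Peaks on the chromosomes (y axis) against the background recovered from the peak values, in fragments (x axis), with 1 point per library (blue, WT; red, Hemgn KO). The deepest library, WT replicate 1, has 47858 peaks at a background of 5.67, and the shallowest, WT replicate 2, has 34181 at 2.29.

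Libraries of one genotype were no more alike than libraries of different genotypes. The Jaccard index of covered base pairs was 0.670 between the WT libraries and 0.694 between the KO libraries. The 4 pairs across genotypes gave 0.666, 0.719, 0.696 and 0.678, and the highest was WT replicate 1 with Hemgn KO replicate 2, the deeper library of each genotype. With lists of equal length the indices within genotype were 0.715 and 0.713, against 0.701, 0.752, 0.693 and 0.696 across genotypes, so the mean difference within minus between turned from -0.00763 to 0.00345.

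Regions exclusive to a genotype were a small part of all regions. Of 55290 merged regions, 27473 (49.7%) were present in all 4 libraries, 1219 (2.2%) were WT-only and 778 (1.41%) were KO-only. The exclusive regions were weak peaks: their median rank was the 16.1 percentile for WT-only and the 15.5 percentile for KO-only, and 72.9% and 77.9% lay in the lowest 25% of ranks. In the upper 50% of ranks in both of their libraries were 43 WT-only and 28 KO-only regions. Exclusive regions lay mostly away from gene boundaries, with 55.9% of WT-only and 53.5% of KO-only regions inside genes and 36.1% and 37.8% outside. The split of WT replicate 1 and Hemgn KO replicate 2 from the other libraries, which are the deeper and the shallower ones, gave more exclusive regions (3993 and 91), and the split by replicate number gave 1024 and 362. In some stricter lists the genotype split had the most exclusive regions in both directions together: 2049 in lists of equal length by q (split by depth 1858, by number 1080), 1127 in the top 20000 by fold (764 and 468), 971 in the top 20000 by q (597 and 301) and 1060 at a fold of at least 6 (887 and 421). In every shortened list, a region also counts as exclusive where the peak of the other pair fell below the cut. Such counts therefore do not show that the other pair lacked a peak. Among regions in the upper 50% of ranks in both of their libraries, the split by depth had the most, 161, against 71 by genotype and 10 by number. In lists of equal length by fold the genotype split had 2040, and the split by depth 2293. The excess of WT-only over KO-only regions was not present with lists of equal length, which gave 1016 and 1024. In the upper 50% of each list there were 355 and 245, and at a fold of at least 6 there were 747 and 313. Leaving out a library asks less of a region: the WT-only count was 2249 without WT replicate 1, 8376 without WT replicate 2 and 3903 without Hemgn KO replicate 2, and the KO-only count was 3976 without WT replicate 1, 4704 without Hemgn KO replicate 1 and 2482 without Hemgn KO replicate 2.

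**Figure D3:**
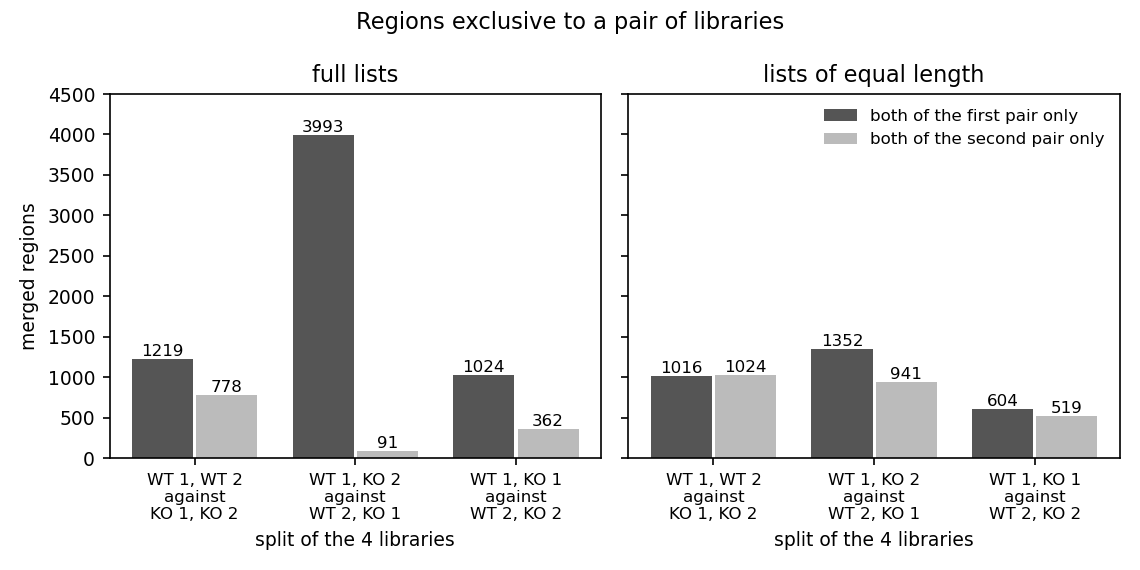
Merged regions (y axis) present in both libraries of one pair and in neither of the other, for the 3 splits of the 4 libraries (x axis), with full lists (left) and lists of equal length (right). Dark bars count the pair named above in each label and light bars the other pair; the genotype split has 1219 and 778 regions with full lists, and the split by depth 3993 and 91.

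The 10 strongest WT-only regions had rank percentiles from 66.7 to 99.4. The highest was a region 41.1 kb from Chrm3, a muscarinic acetylcholine receptor gene (chromosome 13, 9834307 to 9834513), with a rank percentile of 99.4. A region within Akap6, which encodes an anchor of protein kinase A (chromosome 12, 52735129 to 52735729), ranked at the 94.7 percentile. Regions by Ang6, a ribonuclease gene of the angiogenin family (71.9), Klhl1 (71.4), Olfml2b (70.7), Id2, an inhibitor of DNA binding by helix-loop-helix factors (70.4), Mid1 (70.4), Samd4 (68.7), the cohesin loader gene Nipbl (67.4) and Isoc2b (66.7) followed. The Id2 region was 372 kb and the Klhl1 region 165 kb from the nearest gene boundary, so the name Id2 marks a neighbour only. The genes with the most WT-only regions were Ang6 with 4, and Mvb12b, Ybx3, Myo10 and Lipc with 3 each, among 5 genes with that number.

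The strongest KO-only region stood at the boundary of Pnp2, a purine nucleoside phosphorylase gene (chromosome 14, 50955958 to 50956864), at the 86.5 percentile. A region 6.79 kb from Klhl33 (chromosome 14, 50903967 to 50904596) ranked at the 83.1 percentile. Regions by Marveld2, which encodes a tight junction protein (79.7), Nat8f4 (79.3), Ear10, a ribonuclease gene of eosinophils (76.6), Ptprh (72.7), Arhgef28 (67.8), the coagulation gene F5 (67.7), Bmp4, a bone morphogenetic protein gene (66.3), and Sugct (64.4) followed. The Arhgef28, Bmp4 and Sugct regions lay 120, 146 and 171 kb from the boundary that names them. Pnp2, Ear10, Vps35l, Shcbp1l and the autophagy gene Atg7 had 2 KO-only regions each, the highest number for any gene, and were those of highest rank among 50 genes with that number. Ang6, Ear10 and Nat8f4 belong to multigene families, where reads may be placed uncertainly. Whether other named genes, Pnp2 among them, have similar copies was not checked.

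Of the 300 genes in the fixed lists, 199 had a boundary peak in all 4 libraries and 61 in none. A boundary peak in all 4 libraries was found at 19 of 24 heme and iron genes, 19 of 22 red cell membrane genes, 20 of 26 erythroid regulators, 24 of 27 cell cycle genes and 21 of 24 BAF genes. At 5 genes, all markers of other cell types, the boundary peaks separated the genotypes. S100a8, a subunit of the neutrophil protein calprotectin (chromosome 3, 90668876 to 90669263), and Camp, the cathelicidin gene (chromosome 9, 109849074 to 109849689), had a boundary peak in both WT libraries and in neither KO library. Cd79b, part of the B cell receptor (chromosome 11, 106314126 to 106314623), the B cell adaptor gene Blnk (chromosome 19, 40993964 to 40994280) and Pecam1, an endothelial adhesion gene (chromosome 11, 106715142 to 106715563), had one in both KO libraries and in neither WT library. Their rank percentiles were 23.9, 7.21, 25.4, 22.8 and 18.3. Only S100a8 kept this call both with lists of equal length by fold, where Camp did not, and with lists of equal length by q, where Camp, Cd79b, Blnk and Pecam1 did not; none of the 5 kept it in the upper 50% of each list. Exclusive boundary regions were also found at Tmod1, an actin-capping gene of the red cell skeleton (WT-only, 6.13 percentile), Top2a, which encodes a DNA topoisomerase (2 WT-only regions, 5.65 and 2.72 percentiles), and the erythroid cofactor gene Zfpm1 (KO-only, 0.0338 percentile), beside other boundary peaks at these genes in all 4 libraries. The Zfpm1 region had a WT peak within 500 bp.

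No gene list was found to differ between WT-only and KO-only regions, but most lists held too few exclusive regions to pass. With only 2 such regions in a list, Fisher's exact test cannot give a p under 0.150. Among the 16 lists, 0 passed Fisher's exact test after Benjamini-Hochberg adjustment and 0 had an unadjusted p under 0.05; the lowest unadjusted p was 0.150, for 0 WT-only and 2 KO-only regions at megakaryocyte genes (Fli1 and Itgb3) and the same numbers at endothelial and stellate cell genes (Pecam1 and Pdgfra). Without Hemgn KO replicate 1, 1 list passed: hepatoblast and hepatocyte genes had 8 WT-only and 3 KO-only regions (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0327).

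Hepatocyte genes had the lowest p of the 32 tests that set exclusive regions against all reproducible regions. Of 57 reproducible regions at these genes, 7 were WT-only where 1.86 were expected (odds ratio 4.16, 1.88 to 9.19; Fisher's exact test, p = 0.00250), 1 each at the albumin gene Alb, the alpha-fetoprotein gene Afp, Foxa2, Fgg, Ahsg, Cps1 and Krt18, and 2 were KO-only, both at Dlk1. The Benjamini-Hochberg adjusted p over 32 tests was 0.0801, so 0 tests passed, and 1 had an unadjusted p under 0.05. The highest odds ratio was that of 2 KO-only regions at lymphocyte genes (5.93, 1.36 to 25.8). In settings applied to this test after seeing the data, the adjusted p of the list fell under the threshold where regions needed an overlap of 50% (0.00580), in windows around summits (0.0326), with lists of equal length by q (0.00277), without Hemgn KO replicate 1 (0.0357) and without Hemgn KO replicate 2 (0.00192). It did not with lists of equal length by fold (0.0609), on autosomes (0.0780), with a gap of 500 bp (0.251), without WT replicate 1 (0.414) or without WT replicate 2 (0.186). Hepatocyte genes had 0 WT-only regions in the upper 50% of each list, in the top 20000 by fold or by q and at a fold of at least 6, where 0.184, 0.219, 0.205 and 0.275 were expected. Each of the other splits had 1 list past the threshold in the same test: macrophage genes in the split by depth (adjusted p by Fisher's exact test, 0.0308) and erythroid regulators in the split by replicate number (0.00624). In the fixed alternatives, the unadjusted p was 0.142 within classes of region score and 0.0082 against random gene lists, and no list passed. Without Hemgn KO replicate 1, heme and iron genes (1 KO-only region where 9.48 were expected, adjusted p = 0.0285) and endothelial and stellate cell genes (10 KO-only where 3.77 were expected, adjusted p = 0.0357) passed the same Fisher's exact test.

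In the other lists, 0 tests passed and counts were at most 6. Heme and iron genes had 4 WT-only regions where 2.55 were expected (2 at Fech, which encodes the enzyme that inserts iron to form heme, and 1 each at Alas2 and the transferrin receptor gene Tfrc) and 1 KO-only (Slc25a37). Red cell membrane genes had 6 WT-only regions where 4.87 were expected, among them Ank1, Epb41 and Epb42, and 3 KO-only, among them Cd47. Erythroid regulators had 4 WT-only, among them Bach1 and Ikzf1, and 3 KO-only (Bcl11a, Foxo3 and Zfpm1), where 6.18 and 3.91 were expected. BAF genes had 2 WT-only (Bcl7a and Dpf3) and 1 KO-only (Arid1b), with 2.49 and 1.57 expected. Organelle clearance genes had 3 WT-only (Map1lc3b, Rac1 and Xpo7) and 2 KO-only, both at Atg7. Cell cycle genes had 2 WT-only, both at Top2a, and 1 KO-only (Ccnd3); apoptosis genes had 2 WT-only (Pim1 and Trp53) and 0 KO-only. Stem and progenitor cell genes had 1 of each (Hlf and Runx1), as did globin genes. Granulocyte and mast cell genes had 2 WT-only (S100a8 and Camp; 0.556 expected) and 0 KO-only, and lymphocyte genes 1 WT-only (Cd2) and 2 KO-only (Blnk and Cd79b; 0.373 expected). Endothelial and stellate cell genes had 2 KO-only where 0.518 were expected, and megakaryocyte genes 2 where 0.725 were expected. These 4 excesses rest on 2 regions each (Fisher's exact test, unadjusted p of 0.105, 0.0526, 0.0939 and 0.163 in this order). Macrophage genes had 1 WT-only (Csf1r) and 0 KO-only, and housekeeping genes 1 WT-only (Hprt) and 0 KO-only.

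**Figure D4:**
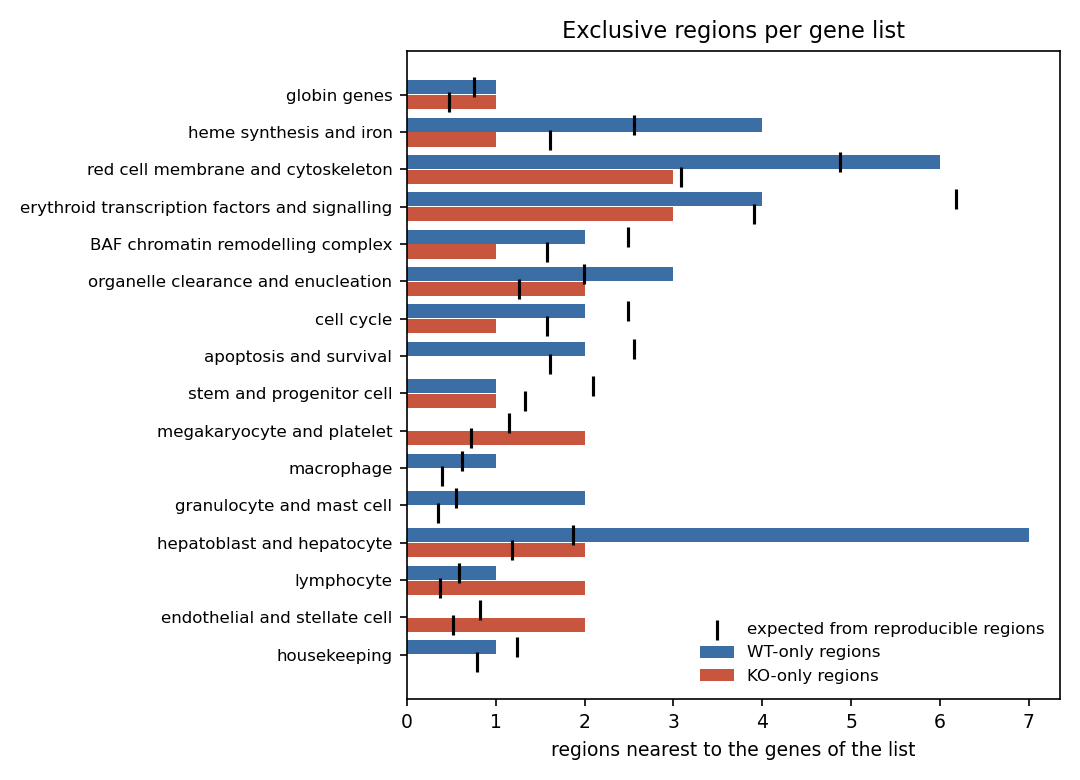
Number of WT-only (blue) and KO-only (red) regions nearest to the genes of each of the 16 lists (x axis, regions; y axis, lists), with a black mark at the number expected from all reproducible regions. The hepatoblast and hepatocyte list has 7 WT-only regions against 1.86 expected.

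Exclusive regions of both genotypes were at gene boundaries about as seldom as regions found in 1 library. The share was 8.04% (6.57 to 9.71) for WT-only regions, 8.74% (6.85 to 10.9) for KO-only regions, 7.99% (7.54 to 8.45) for regions in 1 library, whose median rank was the 15.5 percentile, and 41.4% (40.8 to 41.9) for regions in all 4 libraries. WT-only and KO-only regions did not differ (odds ratio KO over WT 1.10, 0.793 to 1.51; Fisher's exact test, p = 0.618). This changed with the peaks and libraries used: in lists of equal length the shares were 6.99% and 9.67% (odds ratio 1.42; Fisher's exact test, p = 0.0305), in the upper 50% of each list the odds ratio was 2.65 (p = 4.41e-06), without WT replicate 1 it was 1.46 (p = 2.91e-05) and without Hemgn KO replicate 1 it was 0.815 (p = 0.0470). In lists of equal length, the other splits had odds ratios of 2.56 for the split by depth (Fisher's exact test, p = 5.20e-12) and 0.686 for the split by replicate number (p = 0.0785).

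No chromosome held a different share of WT-only and KO-only regions. Among 21 chromosomes, 0 passed Fisher's exact test after adjustment and 1 had an unadjusted p under 0.05, chromosome 19 with 30 WT-only and 34 KO-only regions (p = 0.0260, Benjamini-Hochberg adjusted p = 0.404). Chromosome 4, which carries Hemgn, had 73 and 52, and chromosome X had 37 and 13 (Fisher's exact test, p = 0.0578, adjusted p = 0.404). Peaks on chromosome Y numbered 13 and 14 in WT and 11 and 13 in KO.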

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

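Settings named by q, by the top 20000 peaks or by a fold of at least 6, the crossed pairing and the settings given for lists against reproducible regions were chosen after seeing the data. Region counts moved by over 1.5 times with stricter lists, which hold fewer peaks by construction: WT-only regions numbered 355 in the upper 50% of each list, 545 and 467 in the top 20000 by fold and by q, and 747 at a fold of at least 6, and KO-only regions 245, 504 (by q) and 313. A region exclusive in a stricter list may have a weaker peak, below the cut, in the other genotype. Leaving out 1 library gave 1708 to 8376 WT-only and 940 to 4704 KO-only regions. The KO over WT odds ratio at gene boundaries was 0.891 for a span of 2.5 kb, 2.65 in the upper 50%, 1.42 with equal length and 1.68 with equal length by q, 2.69 and 4.61 in the top 20000 by fold and by q, 2.52 at a fold of at least 6, and 0.815 to 1.46 without 1 library; the cause was not tested, and the split by depth gave 4.13 and 7.04 in the top 20000 by fold and by q, and 1.53 (0.778 to 3.02) at a fold of at least 6, and the split by replicate number 0.239, 0.334 and 0.211, so in each of the 3 settings a split other than genotype was at least as uneven. The mean Jaccard index within minus between genotypes turned to 0.00345 with equal length. KO minus WT ranged from -8636 to 5041 peaks and from -3.09 to 4.43 percentage points of boundary share without 1 library (the cause was not tested). Gene lists past the threshold in the direct test numbered 0 to 1 without 1 library; against reproducible regions they numbered 0 to 3 without 1 library, and 1 each with overlap by 50%, windows around summits and equal length by q (the cause was not tested). Of 31 named regions, the 11 at boundaries of list genes, with ranks of at most the 25.4 percentile, were all lost in the upper 50% of each list, where the 20 chosen for high rank stayed by construction; 24 were kept with equal length, 30 with a gap of 500 bp (not Zfpm1), and 0 reversed. Same-numbered libraries deviated apart (correlation across regions -0.0594 for presence and -0.130 for ranks), but the deeper libraries have different numbers, so whether the number pairs them stays open. With a replicate block the boundary share differed by 0.671 percentage points (exact sign-flip p = 1, smallest possible 0.5), as without it, and the crossed pairing gave the same 0 calls. Motif tests were not run. Depth limits the weakest peaks: the lowest summit had 15 and 9 fragments in WT and 9 and 12 in KO.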

Other observations

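All tests in this part were chosen after the data were seen. The share of each library's regions that lay nearest to the genes of a list, per 10000 regions, separated the genotypes for several lists. Heme and iron genes had 24.3 and 23 in WT and 20 and 20.9 in KO, a KO minus WT change of -13.5%, and red cell membrane genes had 44.5 and 43.0 in WT and 38.7 and 38.3 in KO, a change of -12%. Hepatocyte genes had 16.9 and 14.6 in WT and 12.6 and 13.6 in KO (-16.9%). Granulocyte and mast cell genes had 4.45 and 3.28 in WT and 5.44 and 4.93 in KO (34.2%), although the S100a8 and Camp boundaries were WT-only, and endothelial and stellate cell genes had 7.62 and 6.57 in WT and 8.59 and 8.69 in KO (21.8%). Granulocyte and mast cell genes had only 21, 11, 19 and 21 regions in the 4 libraries, and their change was 16.7% without WT replicate 2 and 58.0% without WT replicate 1. Without 1 library, the change of endothelial and stellate cell genes was 13.4% (WT replicate 2) and that of hepatocyte genes -10.3% (WT replicate 1). Against 10000 random gene lists matched on regions per gene, these 5 of 16 lists passed after Benjamini-Hochberg adjustment (adjusted p 0.0282, 0.0277, 0.0272, 0.0272 and 0.0282), and 7 had an unadjusted p under 0.05. The other splits gave 0 lists each, with lowest adjusted p of 0.0576 and 0.642. Values of both genotypes did not overlap for 7 of 16 lists, where chance gives 5.33 (33.3% for 2 against 2), and 8 lists were separated in the split by depth. Globin genes (2.5%), erythroid regulators (0.256%) and housekeeping genes (-1.29%) had overlapping values. Boundary peaks in all 4 libraries were present at 10 of 20 hepatocyte genes, 6 of 14 endothelial and stellate cell genes and 3 of 15 granulocyte and mast cell genes.

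Depth and weak peaks near the calling threshold remain open for these list shares. The change between deeper and shallower libraries, scaled to the genotypes' difference in background, predicted at most 15% of any of the 5 changes, but this scaling has no spread. With lists of equal length 4 of the 5 lists passed, but so did 4 and 2 lists in the splits by depth and by replicate number, and among the 4 only hepatocyte genes still separated the genotypes. The shallow libraries, WT replicate 2 before Hemgn KO replicate 1, then had the highest shares for heme and iron genes (14.7 and 23.3 in WT, 17.5 and 14.7 in KO) and red cell membrane genes (26.5 and 43.2 in WT, 32.0 and 26.2 in KO), and in the upper 50% of each list 0 lists passed (1 in each of the other splits), 3 of 5 kept their direction, and heme and iron genes turned to 7.84% and granulocyte genes to -42.9%. A lower share of red cell precursors in KO livers may raise markers of all other cell types. Granulocyte and endothelial lists were higher in KO. The stem cell list was higher too (12.2%), without overlap, but did not pass (adjusted p against random gene lists, 0.0955). Means of lymphocyte (7.14%), macrophage (6.57%) and megakaryocyte (4.33%) lists were higher in KO, but their values overlapped and they did not pass. Hepatocyte genes went the other way (-16.9%, and -0.717% in the upper 50%). Among red cell lists, heme and iron (-13.5%), red cell membrane (-12%) and organelle clearance genes (-11.8%) were lower in KO. Globin genes (2.5%) and erythroid regulators (0.256%) were not, with overlapping values. This explanation stays open.

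The strong exclusive regions, those in the upper 50% of ranks in both of their libraries, were grouped on chromosome 14. Of 71 such regions, 12 lay between 40 and 60 Mb of this chromosome, 5 WT-only (3 by Ang6, and Samd4 and Wdhd1) and 7 KO-only (Ear10, Bmp4, Klhl33, Pnp2, Rnase2b, Dhrs2 and Mcpt2); no other window of 20 Mb that does not overlap it had more than 4. Permutation of which reproducible regions are exclusive, within classes of rank, gave at most 9 in any window in 10000 draws (permutation p = 0.0001, the smallest they can give), which argues against chance placement of single regions. Depth is argued against by the split of deeper from shallower libraries, whose own highest window held 6 of 161 strong regions: 71 regions drawn from the 232 of both splits had at most 10 in any window in 10000 draws (permutation p = 0.0001). Both permutations drew regions singly. Some of the 12 lie close together, such as the 3 by Ang6 (44031994 to 44046998), and may not be independent. Both p-values may therefore overstate the evidence. A haplotype of another strain on chromosome 14, shared by the libraries of a genotype, and reads shared between gene copies such as those of the ribonuclease family (Ang6, Ear10 and Rnase2b) may be candidate explanations and were not tested, since sequences were not used here; of 322 reproducible regions in the window, 69.6% were present in all 4 libraries, against 76.4% elsewhere.

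The excess of WT-only over KO-only regions, a ratio of 1.57, may come from depth. Between WT replicate 2 and Hemgn KO replicate 1, whose backgrounds are nearest (1.09-fold apart), 5513 regions were only in the WT library and 6941 only in the KO library, a ratio of 0.794, and the split of deeper from shallower libraries had a ratio of 43.9. In this pair the KO library had the higher background (2.49 against 2.29) and more peaks (35426 against 34181). Its ratio under 1 therefore does not show a reversed excess at equal depth. The excess was absent in lists of equal length (1016 WT-only and 1024 KO-only) but present at a fold of at least 6 (747 and 313). At that fold the split by depth had 807 and 80. A loss of accessible regions in the KO was not shown by the matched pair and is not excluded by it, as 1 pair of libraries carries the test.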
